A study of Mus musculus with 4 samples.

How the data were processed

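Total RNA of mouse myoblasts that the labels call Twist2-positive was sequenced with standard Illumina libraries, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.0, DESeq2 1.6.3 and the genome build GRCm38 (mm10), without saying what each was used for. The read counter, the gene annotation and the strand setting are not given in the sources used here. The authors deposited 1 table of 3760 genes with a CPM value, the reads of a gene scaled to the total of its library, for each library. The authors' deposited table also holds 3 columns of log2 ratios, each against the GFP growth medium library, per the file headers. These columns matched log2((CPM + 1) / (CPM of GFP growth medium + 1)) within 1.3e-11, so the authors' pseudocount was 1 CPM. Their values are used here only for that check.

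The table is a selection. Every listed gene had at least 10 CPM in at least 2 libraries and an absolute log2 ratio of at least 1 in at least 1 of the authors' 3 comparisons, as found from the values. Genes outside that selection were not analysed here, and a gene with at least 10 CPM in a single library cannot be listed. Counts for the comparisons that do not involve the GFP growth medium library therefore cover only genes selected on other comparisons, and the correlations across genes were computed on genes selected in the same way. A gene list's members that are missing from the table are not shown to be unexpressed. Members with an absolute log2 ratio under 1 in all 3 of the authors' comparisons cannot be listed. Shares of genes called 2-fold different thus refer to listed genes, and the selection raises them in comparisons with GFP growth medium.

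All CPM values of every library were whole multiples of the value of 1 read, within 0.001 reads, for 100% of the values, which gave the reads of each gene and the total of each library. The totals were 9744075 (GFP growth medium), 9235281 (GFP differentiation medium), 11068073 (Twist2 growth medium) and 12362290 (Twist2 differentiation medium). Listed genes took 39.3%, 65.1%, 36.9% and 47.2% of these reads. H19 was the most abundant listed gene in 3 libraries, with 1.11%, 2.90% and 2.02% of reads in GFP growth, GFP differentiation and Twist2 differentiation medium, and Vim was highest in Twist2 growth medium, with 1.30%. Of the gene symbols, 3607 were found in the GENCODE M21 annotation of GRCm38, 140 through an older symbol, and 13 were not matched. Positions and transcript lengths come from that annotation.

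Each group had 1 library, so the planned tests for replicated groups were not run, no p-value is given and a count model was not fitted. For each of 4 comparisons a log2 ratio of CPM + 1 was computed, and genes with at least 10 CPM in the higher library were counted as higher or lower at a 2-fold threshold. The difference of the 2 differentiation responses is the log2 ratio in Twist2 cells minus that in GFP cells. From the reads, an exact conditional binomial (Clopper-Pearson) 95% interval was computed for each ratio; reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Comparing the reads of 2 libraries in this way gave an interval that excluded equality for 3524, 3508, 2708 and 3436 of the 3760 genes in the GFP differentiation, Twist2 differentiation, growth medium and differentiation medium comparisons. It held for all 2716, 1895, 555 and 1740 genes counted there as 2-fold different. This compares libraries, not conditions. A gene at 0 reads was compared with a floor of 3 reads per library.

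The 25 gene lists, the comparisons, the thresholds, the rule for named genes and the main alternatives were fixed before the data were examined. They hold 535 entries, of which 268 are in the table. For each list the median log2 ratio, the number of members at least 2-fold higher or lower (without a minimum CPM) and the percentile of the median among 10000 random lists of the same size, matched on mean expression and drawn from the table, were computed as a description of these libraries. Named genes are Twist2, Myod1, Myog, Pax7, Tmem8c (myomaker), Myh3 and Twist1 in each comparison, the 8 highest and 8 lowest ratios among genes with at least 10 CPM in the higher library, and up to 4 members with the largest ratios of each described list plus up to 2 that go 2-fold or more against its median. For the difference of responses the 6 largest and 6 smallest were named. Some genes that this rule selects are not reported here.

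The calculation was tested on simulated counts drawn from the libraries' means and depths. Changes were placed only in genes with a mean of at least 10 CPM in the 2 libraries. In each of the 4 comparisons, with 3760 genes, 100% of 100 genes changed 3-fold and of 100 genes changed 8-fold were recovered and 0% of unchanged genes were called. The intervals covered the true ratio in 96%, 95%, 96% and 97% of the changed genes in the order given above. The simulation holds counting noise alone and no variation between cultures, and it does not show how changes in genes with few reads are recovered.

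The other settings chosen before the data were examined were pseudocounts of 0.1 and 5 CPM, no minimum level or 50 CPM, a 4-fold threshold, libraries centred on the median of all genes, and median-of-ratios size factors. For lists they also included random lists without matching, members above 10 CPM, and the mean. Scaling to the reads of genes outside the table, leaving out genes above 1% of reads, and removing a trend on transcript length were added after the data were seen. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.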

Results

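RNA sequencing was used to ask how forced expression of Twist2, a basic helix-loop-helix transcription factor, altered gene expression in cultured myoblasts, labelled Twist2-positive, from adult mouse skeletal muscle. The myoblasts received a retrovirus carrying either Twist2 or green fluorescent protein (GFP) for 24 h and then spent 24 h in growth medium with 20% fetal bovine serum. Cells were then either harvested or moved to low-serum differentiation medium with 2% horse serum and harvested after 5 days. The 4 groups were thus GFP growth medium, GFP differentiation medium, Twist2 growth medium and Twist2 differentiation medium, with 1 library each. The libraries held 9744075, 9235281, 11068073 and 12362290 reads in that order. Because no group was replicated, no difference given here has a replicate check, and an effect of the library cannot be separated from an effect of the condition. Log2 ratios carry a pseudocount of 1 CPM, which understates the ratio of genes with few reads and affects which genes rank highest or lowest. The 95% counting intervals are for the ratio of the reads without a pseudocount and cover counting error only.

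The virus-encoded gene separated the libraries as their labels state. Twist2 (chromosome 1, 91801461 to 91848028, plus strand, GRCm38) had 1 read in the GFP growth medium library (0.103 CPM, interval 0.0026 to 0.572) and had 0 reads in the GFP differentiation medium library, where the floor of 3 reads in a library corresponds to 0.325 CPM. These values do not show expression of the endogenous gene in the cultured cells, so the name Twist2-positive is the labels' and not a measured state. It reached 1438 CPM (15915 reads, interval 1416 to 1460) in the Twist2 growth medium library and 674 CPM (8335 reads, interval 660 to 689) in the Twist2 differentiation medium library. The log2 counting interval of the ratio in growth medium was 11.30 to 19.08, and in differentiation medium Twist2 was at least 2076-fold higher than in the GFP library. The table does not separate reads of the viral copy from those of the endogenous gene. The related gene Twist1 (chromosome 12, 33957671 to 33959829) stood at 13.6 CPM in GFP and 17.4 CPM in Twist2 cells in growth medium, and at 1.62 and 9.87 CPM after differentiation.

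Differentiation of the GFP cells was examined first, as the reference response of these myoblasts. Genes of the contractile apparatus were far higher after 5 days, and genes of mitosis and DNA replication were far lower. All 41 listed sarcomere genes were at least 2-fold higher (median log2 ratio 5.47, quartiles 4.20 and 7.32), and 44 of 45 mitosis and DNA replication genes were at least 2-fold lower (median -4.57, or -4.58 with genes at 0 reads set to their bound). Each of these medians lay outside the range of 10000 random lists matched on expression, at percentiles of 100 and 0.

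Myh3, the embryonic myosin heavy chain (chromosome 11, 67078300 to 67102291), had the highest ratio with the pseudocount, with 25.9 CPM before and 27313 CPM after (log2 ratio 9.99, counting interval 9.87 to 10.23). The other highest genes were Myh8, Actn2, Ctrb1, Casq2, Myl4, Ablim3 and Capn3, with log2 ratios down to 8.05. Myh8 and Capn3 each had 1 read before differentiation, so their log2 ratios are known only within counting intervals of 10.87 to 18.65 and 8.99 to 16.78; that of Myh8 lies above that of Myh3, which thus ranks highest only because of the pseudocount. Myogenin (Myog, chromosome 1, 134289989 to 134292548), a transcription factor of muscle differentiation, went from 76.4 to 1075 CPM (3.80, interval 3.71 to 3.92). The membrane fusion protein myomaker, listed as Tmem8c (chromosome 2, 27061636 to 27072179), went from 45.6 to 2972 CPM (6.00, interval 5.89 to 6.17). Mef2c, another muscle transcription factor, went from 0.513 CPM (5 reads) to 264 CPM. Myod1 (chromosome 7, 46376474 to 46379099) was 1184 CPM before and 810 CPM after (-0.55, interval -0.59 to -0.51), and the satellite cell factor Pax7 (chromosome 4, 139737062 to 139833528) was 78.7 CPM before and 4.01 CPM after (-3.99). Twist1 was lower after differentiation (-2.48).

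Other muscle groups were also higher, among the members that the selection of genes left in the table. The table held 41 of 53 sarcomere names, 21 of 31 coupling and junction names, 14 of 21 metabolism names and 12 of 23 fusion names. Of 21 genes of excitation-contraction coupling and the neuromuscular junction, 18 were at least 2-fold higher (median 2.51), among them Casq2 (8.51), Cacna1s (7.53), Srl (6.87) and Hrc (5.83). Of 14 genes of muscle energy metabolism, 13 were higher (median 4.31), including Mb (7.36), which encodes myoglobin, and Ckm (6.47), which encodes muscle creatine kinase. All 7 fast-fibre genes were higher (median 5.47), among them Tnnc2 (7.83) and Myh1 (7.03). All 7 slow-fibre genes were higher too (median 7.17, or 7.30 with genes at 0 reads set to their bound), among them Myh7 (7.88) and Tnni1 (7.30). Several fibre-type genes also belong to the sarcomere list. Fusion genes were mixed, with 5 of 12 higher and 3 lower (median 0.48), and Kirrel (-2.67) stood against Tmem8c and Dysf (3.09). The 10 myogenic regulators split into 4 higher and 4 lower, with a median of -0.50 but a mean of 0.76, and the median turned to 0.30 when libraries were scaled to the reads outside the table.

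On the lower side, the proliferation marker Mki67 was 248 CPM before and 0.433 CPM (4 reads) after (-7.44). Scn9a, Id3, Cenpe, Top2a, Cenpa, Hmmr and Akap12 completed the 8 lowest genes. Cenpa and Hmmr had 1 and 3 reads after differentiation, with log2 counting intervals of -14.63 to -6.84 and -10.26 to -6.43. E2f2 (1.51) was the single higher gene of the mitosis and replication list. Among 8 cell cycle inhibitor and exit genes, 3 were higher, including Cdkn1a (2.03, 787 CPM before and 3223 CPM after), which encodes the inhibitor p21, and 1 was lower, Rbl1 (-1.71). Extracellular matrix genes were mainly lower, 18 of 32 (median -1.46), as seen for Tnc (-5.54), Col8a1 (-5.41) and Fbln2 (-5.21), whereas Adamts1 (6.59) and Adamts5 (4.20) were higher. Of the 4 listed fibro-adipogenic progenitor and fibroblast markers 2 were lower and 0 higher (median -1.41, or -0.63 under the outside-table scaling). Of 19 genes of the TGF-beta and BMP pathways, 10 were lower and 5 higher (median -1.10), with Id1 (-5.36) opposed by Fst (5.47). Of 13 mesenchymal transition genes, 10 were lower (median -1.77), among them Snai2 (-2.78). Of 15 satellite cell and myoblast surface or signalling genes, 8 were lower and 5 higher (median -1.71), with Notch3 (-4.41), Cxcr4 (-4.21) and Met (-3.57) on the lower side and Spry1 (3.06) on the higher. Under the outside-table scaling the medians were -0.68 for matrix (13 lower), -0.31 for TGF-beta and BMP, -0.98 for mesenchymal transition (6 lower) and -0.92 for satellite cell and myoblast genes (6 higher and 7 lower), 1.25 for fusion genes and 1.32 for cell cycle exit genes.

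Across the 3694 genes that reached 10 CPM in the higher of the 2 GFP libraries, 1205 were at least 2-fold higher and 1511 at least 2-fold lower after differentiation, so 44.4% of these differences were on the higher side. That share depended on scaling. The genes of the table held 39.3% of the reads before and 65.1% after differentiation. The share was 58.5% with median-of-ratios size factors and 69.8% when libraries were scaled to the reads outside the table, where 646 genes were lower. These scalings shifted the median of all genes by 0.34 and 0.78 on the log2 scale.

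**Figure D1:**
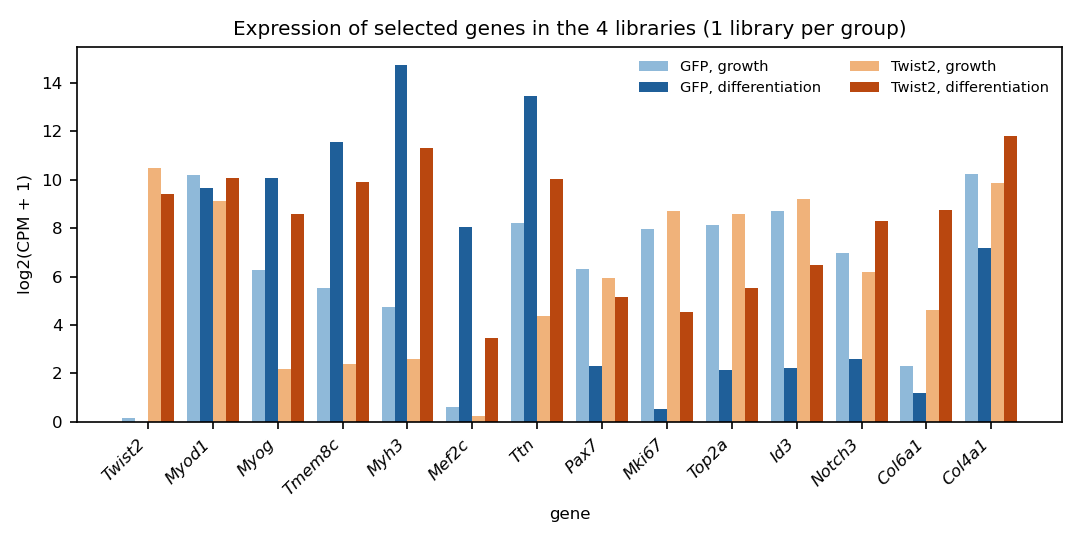
Bars give log2(CPM + 1) of 14 genes (horizontal axis) in the 4 libraries, 1 bar per library and no error bars because no group was replicated. Twist2 is high only in the bars of the Twist2 libraries, and Myh3 and Ttn are highest in the GFP differentiation medium library, at 27313 and 11355 CPM.

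Differentiation of the Twist2 cells was then measured in the same way, to ask whether cells with forced Twist2 still mounted this response. Muscle genes were again higher, and most listed mitosis and DNA replication genes were lower, after 5 days. All 41 sarcomere genes were at least 2-fold higher (median log2 ratio 5.84, percentile 100). Of 45 mitosis and DNA replication genes, 35 were at least 2-fold lower (median -2.87, percentile 0), with E2f2 (3.40) again higher. The 9 in between were the replication-related genes Mcm3 (-0.10), Mcm4 (-0.43), Mcm5, Mcm6 (-0.95), Pcna (-0.09), Tyms, Cdt1, Gins2 and Cdc45. Mcm7 (-1.28) and Rrm2 (-1.79) were lower. Of 32 extracellular matrix genes, 18 were higher and 1 was lower (median 1.27, percentile 99.98), where the GFP cells had 8 higher and 18 lower; that difference between the viruses was not tested.

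Myh3 again had the highest ratio with the pseudocount, with 5.06 CPM before and 2528 CPM after (8.71, counting interval 8.59 to 9.37). Myl4, Tnnc2, Mybph, Acta1, Actc1, Mylpf and Myl1, all components of muscle filaments, followed with log2 ratios from 8.36 to 7.55. Without the pseudocount Tnnc2 (1.36 CPM before and 723 CPM after) lies above Myh3. Myog went from 3.52 to 378 CPM (6.39, interval 6.29 to 7.24), Tmem8c from 4.25 to 963 CPM (7.52, interval 7.41 to 8.27) and Myod1 from 547 to 1068 CPM (0.96, interval 0.92 to 1.01). Pax7 was 60.5 CPM before and 34.6 CPM after (-0.79), and Twist1 17.4 and 9.87 CPM (-0.76). Twist2 itself was lower after differentiation (-1.09, interval -1.13 to -1.05). The 8 lowest genes were Scn9a (-6.20), Cenpf (-5.19), Atoh8, Aspm, Cenpe, Rgs4, Pcolce2 and Casc5 (-4.48). Of these, Scn9a, Cenpf, Aspm, Cenpe and Casc5 have transcripts in the longest of 5 length groups (at least 6230 bp). The median ratio of listed genes ran from 0.47 in the shortest group to -0.51 in the longest, against -0.12 and -0.26 in GFP differentiation. A part of these low ratios may thus go with length in the library, which was not corrected here. Reads of closely related genes, such as the myosin heavy chains and the muscle actins, may have been divided between copies in the authors' counting, which the sources used here do not describe.

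Of 21 coupling and neuromuscular junction genes, 18 were higher (median 3.50), led by Casq2 (7.05), Hrc (6.97), Cacna1s (6.76) and Trdn (6.03). Of 14 energy metabolism genes, 11 were higher (median 3.88), among them Ckm (6.01) and Pygm (5.84). The 7 fast-fibre genes (median 5.49) and the 7 slow-fibre genes (median 6.14) were all at least 2-fold higher. Among fusion genes 6 of 12 were higher and none was at least 2-fold lower (median 1.05). Of 10 myogenic regulators, 4 were higher and 0 lower (median 0.82), and Mef2c reached 10.03 CPM from 2 reads before (log2 counting interval 3.91 to 8.86). The cell cycle exit genes Cdkn1a (2.58), Ccnd3 (2.30) and Btg2 (2.12) were higher, and Ccng1 (-1.11) and Rbl1 (-1.01) lower (list median 0.59), but 0 were lower and 4 higher under the outside-table scaling, and 1 was lower with a pseudocount of 5 CPM. Collagen genes led the matrix list, with Col12a1 (4.65), Col6a1 (4.13), Col11a1 (3.79) and Col6a3 (3.44) higher and Col1a2 (-2.11) lower. Of 15 satellite cell and myoblast genes, 9 were higher and 3 lower (median 1.71), with Spry1 (4.32) and Hey1 (2.61) on the higher side and Met (-2.23) and Vcam1 (-1.22) on the lower. Under the outside-table scaling 9 were higher and 1 lower (median 1.97). Chodl, of the same list, had 0 reads before differentiation and was at least 46.6-fold higher after it. Of 13 mesenchymal transition genes, 5 were lower, including Snai2 (-2.14) and Vim (-1.62), and Zeb1 (1.53) was higher (median -0.88). Of 19 TGF-beta and BMP genes, 10 were lower and 6 higher (median -1.26, mean -0.42), with Id1 (-3.31) on the lower side and Fst (4.81) on the higher.

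Among 3715 genes that reached 10 CPM in the higher library, 984 were at least 2-fold higher and 911 at least 2-fold lower, a higher share of 51.9%. With scaling to the reads outside the table the median of all genes shifted by 0.25, 604 genes were lower and the higher share was 66.8%. The authors' table holds only genes that passed a filter against the GFP growth medium library, so these counts leave out genes that differed between the Twist2 libraries alone.

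The effect of Twist2 before differentiation was read from the growth medium libraries. Most sarcomere and coupling genes were lower with Twist2, and the matrix list had more higher than lower genes. Of 41 sarcomere genes, 30 were at least 2-fold lower and none was higher (median log2 ratio -2.19, percentile 0). Of 21 coupling and neuromuscular junction genes, 19 were lower (median -1.68, percentile 0), among them the acetylcholine receptor subunit genes Chrng (-3.59) and Chrnd (-3.39). Of 32 matrix genes, 13 were higher and 1 was lower (median 0.78, percentile 100).

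Myog had the lowest ratio with the pseudocount, with 76.4 CPM in GFP and 3.52 CPM in Twist2 cells (-4.10, counting interval -4.94 to -3.97). Ccdc141, Pdlim3, Lmod3, Ttn, Ppfia4, Myom3 and Ano5 were the next lowest, from -3.99 to -3.77. Without the pseudocount some genes with fewer reads lie below Myog, such as Trdn (19.2 CPM in GFP and 0.723 CPM in Twist2 cells). Titin (Ttn) was 297 CPM in GFP and 19.8 CPM in Twist2 cells. Tmem8c (-3.15, interval -3.89 to -2.99), Myh3 (-2.15, interval -2.80 to -1.93) and Myod1 (-1.11, interval -1.16 to -1.07) were lower as well, whereas Pax7 (-0.37) and Twist1 (0.33) differed by less than 2-fold. Besides Twist2 itself, the highest genes were Il1rl1, Lrrc32 (3.87), Ankrd35, Col16a1 (3.66), Crabp1 (3.53), Runx1t1 (3.24) and Fam20a (3.04). Il1rl1, a receptor for interleukin 33, had 0 reads in the GFP library and 26.7 CPM in the Twist2 library, at least 86.6-fold higher. Ankrd35 had 3 reads in the GFP library (log2 counting interval 4.15 to 8.01).

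None of 10 myogenic regulators was at least 2-fold higher and 5 were lower (median -0.83), including Mef2a (-1.95). Of 15 satellite cell and myoblast genes, 6 were lower (median -0.79), with Cxcr4 (-2.19), Met (-1.35) and Cdh15 (-1.29), but only 3 were lower with median centring, and 3 were lower and 1 higher with size factors (median -0.57). Of 14 metabolism genes, 5 were lower (median -0.60), led by Pdk4 (-2.22), and of 12 fusion genes 4 were lower and 1, Adam12 (1.91), was higher (median -0.50). Fast-fibre genes (6 of 7 lower, median -2.40) and slow-fibre genes (3 of 7 lower, median -0.94) had negative medians. With a pseudocount of 5 CPM the medians of regulators, fast-fibre and slow-fibre genes were -0.50, -1.58 and -0.43, and with 0.1 CPM they were -1.09 (6 of 10 lower), -3.14 and -1.71 (5 of 7 slow-fibre genes lower). With size factors those of metabolism, fusion and TGF-beta and BMP genes were -0.36, -0.26 and 0.57, and 17 matrix genes were higher, and 16 coupling genes, 3 regulators and 2 cell cycle exit genes lower. Mitosis and replication genes had a median of 0.61 (percentile 100), and 5 of 45 were at least 2-fold higher, among them Cdc20 (1.16) and Plk1 (1.07), and E2f2 was lower (-2.42). That count was 11 with median centring and 16 with size factors (median 0.85), and it fell with a pseudocount of 5 CPM and with the outside-table scaling. Of 8 cell cycle exit genes 4 were lower, such as Gadd45a (-1.45) and Rb1 (-1.33), and Cdkn2b (1.10) was higher (median -0.90). In the matrix list Col6a3 (2.56), Col6a1 (2.31) and Dcn (1.97) were higher and Timp3 (-1.18) lower. The mesenchymal transition genes Prrx2 (1.85), Itgb3 (1.84), Cdh11 (1.72) and Snai2 (1.65) were higher, 4 of 13 with none lower (median 0.53), and 5 of 19 TGF-beta and BMP genes were higher, led by Grem1 (2.82), with Fst lower (-1.78; median 0.33). Of the 4 listed markers of fibro-adipogenic progenitors and fibroblasts, 2 were higher beside the matrix genes, Cd248 (2.33) and Ly6a (1.5), and the median was 1.23.

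In all, 183 of 3514 genes were at least 2-fold higher with Twist2 and 372 at least 2-fold lower, a higher share of 33.0%. Median-of-ratios scaling shifted the median of all genes by 0.23, left 238 genes lower and moved the higher share to 53.0%. Of the 372 lower genes, 168 were at least 2-fold higher in the GFP cells after differentiation and 54 at least 2-fold lower.

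The same comparison after 5 days of differentiation asked how far the Twist2 cells differed from GFP cells at the end of the protocol. Sarcomere genes were lower in the Twist2 library, and genes of mitosis and of the matrix were higher. Of 41 sarcomere genes 40 were at least 2-fold lower (median -2.04, quartiles -2.64 and -1.80, percentile 0). Of 45 mitosis and replication genes 42 were at least 2-fold higher (median 2.28, or 2.33 with genes at 0 reads set to their bound, percentile 100), and with a pseudocount of 5 CPM 31 were (median 1.23). Of 32 matrix genes 25 were higher and 3 lower (median 3.74, percentile 100), and 3 of the 4 listed fibro-adipogenic progenitor and fibroblast markers were higher beside them (median 1.95, or 2.20 with genes at 0 reads set to their bound).

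Collagen VI genes were prominent among the highest ratios. Col6a1 was 1.30 CPM in GFP and 434 CPM in Twist2 cells (7.56, counting interval 7.58 to 9.34), and Col6a3 was 0.650 and 195 CPM (6.89). Mrc2 (7.0), Tnc (6.89), Plat (6.58), Col5a3 (6.21) and Gja1 (6.14) completed the highest genes besides Twist2 itself. At the other end, Mef2c was 264 CPM in GFP and 10.03 CPM in Twist2 cells (-4.59, interval -4.99 to -4.46). The nuclear RNA Malat1 was 3610 and 236 CPM (-3.93, interval -3.99 to -3.88). Fsd1l (-3.79), Myh8 (-3.69), Capn3 (-3.65), Ttn (-3.46) and Myh3 (-3.43) were among the next lowest. Ratios in this comparison also fell with transcript length, from a median of 0.38 in the shortest of 5 length groups to -0.78 in the longest. Mef2c, Malat1, Fsd1l and Ttn are in the longest group, and their ratios are not corrected for this trend. Myh3 stood at 27313 CPM in GFP and 2528 CPM in Twist2 cells (interval -3.45 to -3.42). Myog (-1.51, interval -1.56 to -1.46) and Tmem8c (-1.62, interval -1.66 to -1.59) were lower, Myod1 differed little (0.40, interval 0.36 to 0.44), and Pax7 (2.83, interval 2.63 to 3.64) and Twist1 (2.05, interval 1.82 to 3.48) were higher.

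Coupling and neuromuscular junction genes were lower in 14 of 21 cases (median -1.41), such as Trdn (-2.48) and Srl (-2.33), and energy metabolism genes in 10 of 14 (median -1.28), such as Cox6a2 (-1.81) and Slc2a4 (-1.78). All 7 fast-fibre genes (median -1.82) and 5 of 7 slow-fibre genes (median -2.34) were lower. Fusion genes were split, 4 higher and 4 lower, with a median of 0.04 that turned to -0.02 and -0.55 under the size-factor and outside-table scalings. The 10 myogenic regulators had 2 higher and 3 lower (median -0.43). Among cell cycle exit genes Rb1 was lower (-1.95) and Btg2 higher (1.52; median -0.47). On the higher side were Mki67 (4.0, 0.433 CPM in GFP and 22.0 CPM in Twist2 cells), Tpx2 (3.47), Ccna2 (3.45) and Top2a (3.39). Of 15 satellite cell and myoblast genes 8 were higher (median 1.19, percentile 99.61), including Notch3 (5.71), Hey1 (3.88) and Cxcr4 (3.10), and Des was lower (-1.15); the outside-table scaling gave 4 higher and 4 lower (median 0.60). Of 13 mesenchymal transition genes 6 were higher and 0 lower (median 0.94), led by Cdh11 (4.47) and Itgb3 (4.04). Of 19 TGF-beta and BMP genes 9 were higher and 3 lower (median 0.85), with Inhbb (5.11) and Id3 (4.24) against Fst (-2.43). In the matrix list Adamts5 (-1.53) and Has2 (-1.29) were lower. The outside-table scaling gave medians of -1.02 for regulators (1 higher and 5 lower), -1.06 for cell cycle exit genes (0 higher and 5 lower), 0.34 for mesenchymal transition genes (4 higher and 2 lower) and 0.32 for TGF-beta and BMP genes (9 higher and 7 lower).

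In total 873 of 3437 genes were at least 2-fold higher and 867 at least 2-fold lower with Twist2, a higher share of 50.2%. Scaling to the reads outside the table shifted the median of all genes by -0.57, gave 497 higher and 1548 lower genes and reduced the higher share to 24.3%.

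**Figure D2:**
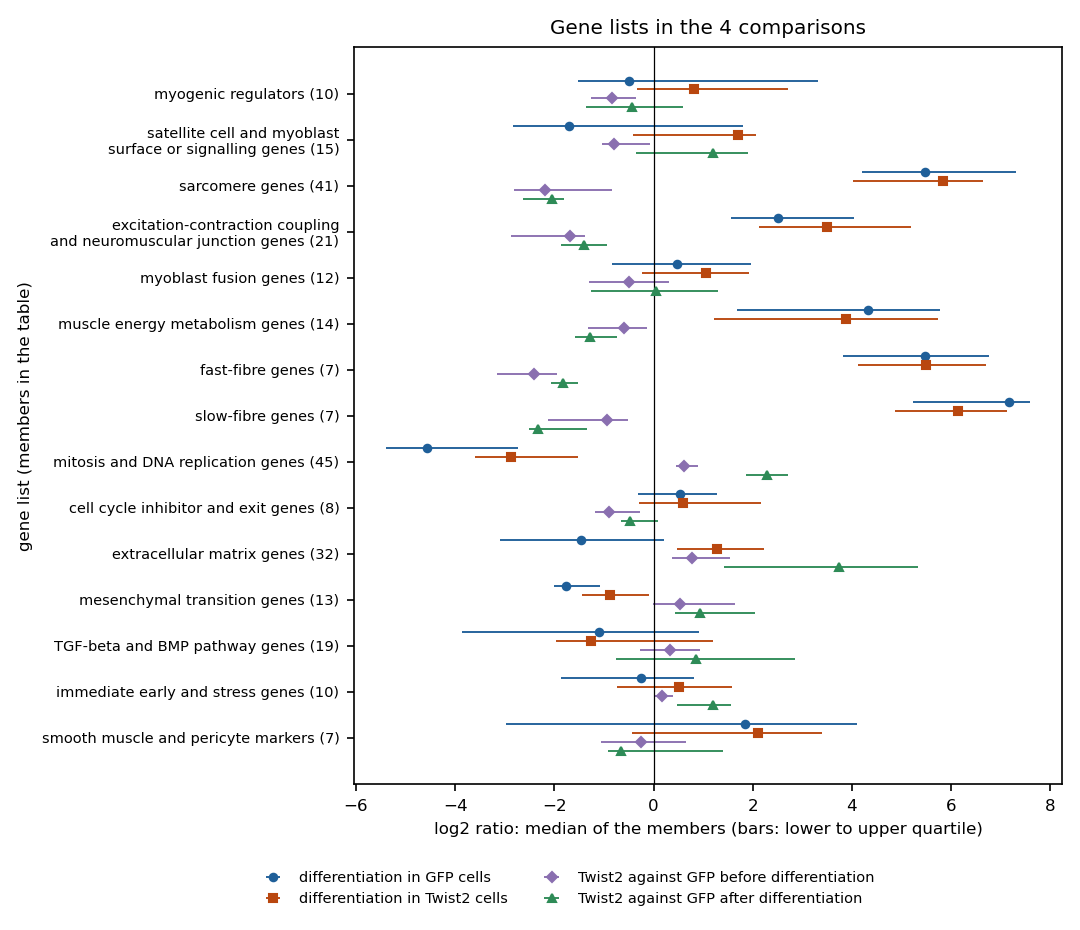
Points are median log2 ratios of the members of each list (horizontal axis) for the lists with at least 7 members in the table, and bars run from the lower to the upper quartile of the members. Sarcomere genes lie at 5.47 and 5.84 in the differentiation comparisons and at -2.19 and -2.04 in the comparisons of Twist2 with GFP, and matrix genes lie at -1.46 in GFP and 1.27 in Twist2 differentiation. The fusion gene median of 0.04 changes sign with scaling.

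The 2 differentiation responses were finally compared with each other by subtracting the log2 ratio of the GFP cells from that of the Twist2 cells. Their directions were largely shared, and matrix genes and mitosis and replication genes had positive median differences. Across the 3760 genes the responses had a Pearson correlation of 0.81 and a Spearman correlation of 0.73, with the same sign in 84.6% of genes. These values are across genes, which are not independent replicates. The pair shares no library. The corresponding values for the Twist2 effects before and after differentiation were 0.56, 0.60 and 74.4%. Of the genes called in either response, 761 were higher in both and 607 lower in both. A further 438 were at least 2-fold higher in GFP cells and in between in Twist2 cells, and 867 were at least 2-fold lower in GFP cells and in between in Twist2 cells. Conversely, 186 were at least 2-fold higher and 298 at least 2-fold lower in Twist2 cells and in between in GFP cells.

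The difference of responses was positive for 37 of 45 mitosis and replication genes at the 2-fold level (median 1.55, or 1.66 with genes at 0 reads set to their bound, percentile 100), led by Mki67 (3.28), Ccnd1 (2.98) and Top2a (2.90), but for only 12 of 45 with a pseudocount of 5 CPM (median 0.55) and for 41 with 0.1 CPM (median 2.34). At that level it was also positive for 24 of 32 matrix genes (median 2.99, percentile 100), including Tnc (6.11), Col8a1 (5.46) and Col6a1 (5.25), against Adamts1 (-3.25). Sarcomere genes had a median near 0 (0.19) that turned to -0.12 and -0.42 under the size-factor and outside-table scalings and to -0.47 with a pseudocount of 5 CPM, and Myh8 (-4.09), Myh1 (-3.03) and Actn2 (-3.02) stood lowest. Coupling genes had a median of 1.04, with 11 of 21 positive by at least 1 log2 unit, the level of all counts in this paragraph. The medians were -0.32 for metabolism genes, 0.54 for fusion genes, 0.57 for fast-fibre genes and -0.32 for slow-fibre genes. They were 0.62 for cell cycle exit genes and 0.54 for TGF-beta and BMP genes. These medians depended on settings. The coupling median was 0.21 with a pseudocount of 5 CPM, 0.73 with size factors (5 positive and 5 negative) and 0.37 with the outside-table scaling (4 and 5). The outside-table scaling gave -0.86 for metabolism, 0.01 for fusion, 0.00 for fast-fibre, -0.86 for slow-fibre, 0.10 for cell cycle exit and 0.08 for TGF-beta and BMP genes. The fast-fibre median was 1.27 with a pseudocount of 0.1 CPM and 0.21 with 5 CPM, where the slow-fibre and the TGF-beta and BMP medians were -0.65 and 0.05. Mesenchymal transition genes had a median of 0.45, which turned to -0.09 under the outside-table scaling. Myogenic regulators had a median of 1.13 and satellite cell and myoblast genes one of 1.21, with Pax7 (3.20), Myog (2.59) and Cxcr4 (5.29), but under the outside-table scaling these medians were 0.65 (3 positive and 3 negative) and 0.69 (4 and 1). Myod1 (1.51), Tmem8c (1.53) and Twist1 (1.72) were positive, and Myh3 was negative (-1.28). A positive difference here does not mean a higher level with Twist2 after differentiation. Myog and Tmem8c began at 3.52 and 4.25 CPM in Twist2 cells, against 76.4 and 45.6 CPM in GFP cells. After differentiation they stood at 378 and 963 CPM in Twist2 cells, against 1075 and 2972 CPM in GFP cells. The coupling list was likewise lower with Twist2 before (median -1.68) and after differentiation (median -1.41). The 6 largest differences were Mest (6.69), Notch3 (6.52), Igfbp3 (6.35), Sox8 (6.22), Tnc (6.11) and Timp3 (5.64). The 6 smallest were Mef2c (-4.23), Npr3 (-4.20), Myh8 (-4.09), Capn3 (-3.96), Malat1 (-3.90) and Prkg1 (-3.66). In all, 958 genes were at least 1 log2 unit more positive in Twist2 cells and 473 more negative, a higher share of 66.9% that became 47.4% with size factors (777 more negative) and 34.8% with the outside-table scaling (568 and 1065 genes). Those scalings shifted the median difference by -0.29 and -0.52.

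**Figure D3:**
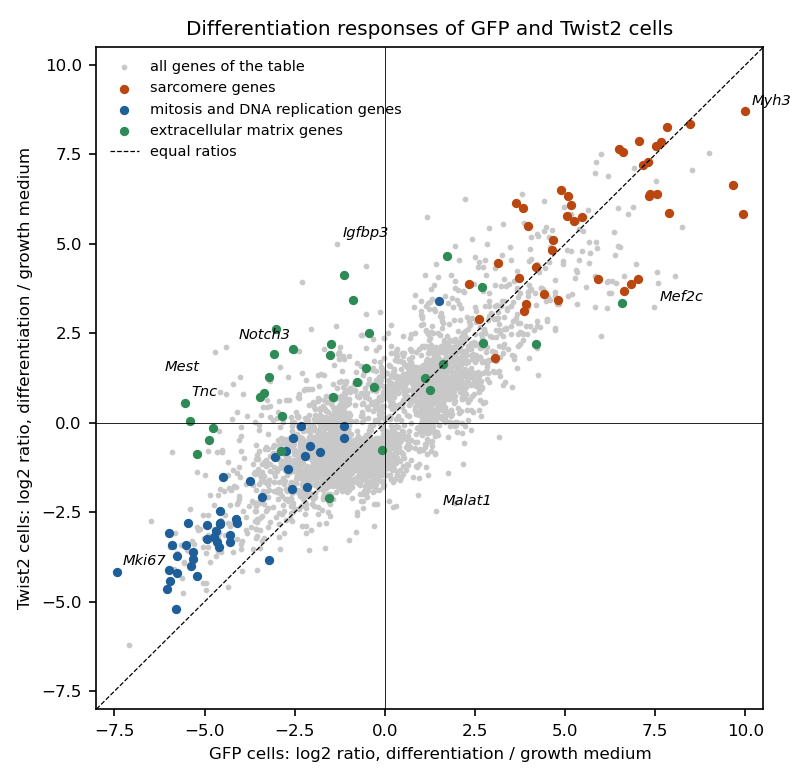
Each point is a gene of the table, placed by its log2 ratio of differentiation over growth medium in GFP cells (horizontal axis) and in Twist2 cells (vertical axis), with 3 gene lists coloured and the line of equal ratios dashed. Sarcomere genes lie at the upper right on both sides of the line, most mitosis genes lie above it at the lower left, and many matrix genes lie in the upper left, as for Timp3 (-3.01 and 2.62).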

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

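The scaling to the reads outside the table, the count of opposite genes that kept their 2-fold differences under it, the rule that reads it together with the first count and the test of fibroblast markers were chosen after the results were seen. None of the differences between the virus groups in this part was tested, since each group is 1 library.

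A total of 43 genes went in opposite directions by at least 2-fold in the virus groups, 37 lower after differentiation in GFP and higher in Twist2 cells and 6 the other way. Their number ranged from 6 with a 4-fold threshold to 48 without a minimum level. They include 6 matrix genes and 3 satellite cell and myoblast genes. The median of the matrix list was -1.46 in GFP and 1.27 in Twist2 cells (difference of responses 2.99), and the median of the satellite cell and myoblast list was -1.71 and 1.71 (median difference of the members 1.21). Most members of the satellite cell and myoblast list kept their sign in both groups, and only Cxcr4, Notch3, Hey1 and Hes1 changed it.

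Among genes named by the rule, Mest went from 793 to 29.1 CPM in GFP cells and from 139 to 548 CPM in Twist2 cells (difference 6.69). Notch3, a Notch receptor, went from 126 to 4.98 and from 71.5 to 313 CPM (6.52). Igfbp3 went from 308 to 121 and from 47.3 to 1553 CPM (6.35). Sox8 went from 17.7 to 2.82 and from 0.723 to 25.2 CPM (6.22). Timp3, a metalloproteinase inhibitor, went from 35.9 to 3.57 and from 15.3 to 99.3 CPM (5.64). Cxcr4 went from 65.5 to 2.60 and from 13.6 to 29.9 CPM (5.29). Hey1, a Notch target, went from 12.6 to 2.27 and from 6.87 to 47.1 CPM (4.67). Spp1, which encodes osteopontin, went from 1242 to 221 and from 917 to 3707 CPM (4.50). In the other direction, Npr3 went from 14.4 to 58.6 and from 29.5 to 5.42 CPM (-4.20), and Malat1 from 1340 to 3610 and from 1317 to 236 CPM (-3.90).

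With libraries scaled to the reads outside the table, the first count made was of all genes opposite by 2-fold, 42 (27 and 15 in the respective directions), above the bound of 24 set for excluding scaling, but of the 43 genes themselves only 21 kept both 2-fold differences (17 and 4), below it. The counts fall on both sides of the bound and cannot decide on scaling to all reads. Scaling to the reads outside the table raises all ratios of GFP cells. It took the median of the 37 genes there from -1.76 (quartiles -2.70 and -1.29) to -1.04 (quartiles -1.99 and -0.55). In Twist2 cells the median of these genes was then 2.02 (quartiles 1.42 and 2.30). The genes going the other way then had medians of 2.36 (quartiles 2.04 and 2.67) in GFP and -1.19 (quartiles -1.80 and -1.03) in Twist2 cells. This scaling shifted the median of all genes by 0.78 in GFP and 0.25 in Twist2 differentiation. Both shifts are smaller than the 1 log2 unit at which the genes were selected. The directions of each set were thus kept by construction and do not decide on scaling to all reads. The 2-fold size of the differences of single genes did depend on scaling. More fibroblast-like cells in the Twist2 culture after differentiation would raise fibroblast markers there. The listed markers had a median of -0.62 (quartiles -1.72 and 0.10), with 2 of 4 lower and 0 higher, which goes against this explanation. Compared with GFP cells after differentiation, however, 3 of these 4 markers were at least 2-fold higher (median 1.95). The explanation by fibroblast-like cells is left open, because only 4 of the 15 names of that list are in the table. The bound set for excluding it was met, and the requirement on listed names was added after the value was seen. A response of the cells to Twist2 may account for these genes and was not tested apart from the library.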

How the results depend on the processing

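Scaling to the reads outside the table, leaving out genes above 1% of reads and removing the length trend were chosen after the data were seen; the other alternatives were planned. The side with more genes changed under some settings. Pseudocounts, median centring, no minimum level and leaving out abundant genes kept every count of the comparisons within 1.5 times, as did removing the length trend in the comparison after differentiation, the only one where it was run. With a minimum of 50 CPM, fewer genes are tested, and the counts were 709 lower in GFP differentiation, 635 higher and 475 lower in Twist2 differentiation, 96 higher and 212 lower with Twist2 in growth medium, 415 higher after differentiation and 587 more positive in the difference of responses. The stricter 4-fold threshold gave 451 higher and 545 lower, 420 and 209, 36 and 97, 338 and 178, and 292 and 75 in the same order. Median-of-ratios size factors gave 1325 higher and 939 lower in GFP differentiation, 268 and 238 in growth medium, and 699 more positive and 777 more negative differences, each with the larger side turned. Scaling to the reads outside the table gave 1490 higher and 646 lower in GFP differentiation, 604 lower in Twist2 differentiation, 497 higher and 1548 lower with Twist2 after differentiation, and 568 more positive and 1065 more negative differences. In the comparison after differentiation the sides were nearly equal at first, and several settings turned the larger one. Both scalings shift all genes of a library together. Shares of higher genes also moved with the 50 CPM minimum (56.7% in GFP differentiation, 39.0% with Twist2 after it) and with the 4-fold threshold (66.8% in Twist2 differentiation, 65.5% with Twist2 after it, 79.6% for the difference). Against counting intervals, which are narrow here, 276 gene list medians under the alternatives stayed inside and 274 moved outside. Of the values of named genes 1524 lay inside and 861 outside, and no list median or named gene at 2-fold or more changed sign. In the 4 comparisons the intervals of named genes are for ratios without a pseudocount. A main value can thus lie outside its own interval, as for Col6a1 with Twist2 after differentiation, so the 861 do not all reflect a change of setting. No paired analysis was possible because each comparison sets 1 library against 1; DESeq2, edgeR and leaving out replicates were not run for that reason. Depth limits genes with few reads, whose counting intervals are wide.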

Other observations

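The tests of scaling and of a single mixing share and the removal of the length trend were chosen after the results were seen, as was the set of ribosomal protein genes.

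Lists outside the muscle programme were represented by few genes. Smooth muscle and pericyte markers had medians of 1.84 in GFP and 2.11 in Twist2 differentiation (7 genes), led by Acta2 (4.46 and 5.47) and Abcc9 (5.31 and 4.27), against Rgs5 (-5.57 and -3.92); their medians with Twist2 were -0.26 before and -0.65 after differentiation, the latter -1.25 under the outside-table scaling. Immediate early and stress genes (10 genes) had medians of -0.25 in GFP differentiation, which turned to 0.53 under the outside-table scaling, and 0.52 in Twist2 differentiation, and 6 of them were at least 2-fold higher with Twist2 after differentiation (median 1.20, or 0.61 with 3 higher under the outside-table scaling), among them Ier2 (2.14) and Fos (1.40). Of 3 cartilage and bone markers all 3 were lower with GFP differentiation (median -2.49), and with Twist2 after differentiation Spp1 (4.06) and Sox9 (1.54) were higher (median 1.54). The 4 cytokine and chemokine genes had a median of 2.87 with Twist2 after differentiation, or 2.89 with genes at 0 reads set to their bound, with Cxcl12 (4.91) higher and Ptgs2 (-1.98) lower. The corresponding medians were 0.52 for 4 interferon-stimulated genes and 0.50 for 3 glial and neural markers, which turned to -0.06 and -0.05 under the outside-table scaling, -1.0 for 3 adipocyte markers and 1.17 for 3 tendon markers. No endothelial, leukocyte or haemoglobin gene was listed, 0 of 12, 17 and 7 names.

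The 20 ribosomal protein genes in the table were all at least 2-fold lower in GFP differentiation (median -1.15), which the selection of genes 2-fold different from GFP growth medium largely fixes. With scaling to the reads outside the table the median was -0.39 and 0 of 20 were.

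After differentiation the sarcomere genes were lower with Twist2, and 3 explanations were weighed. Ratios of Twist2 over GFP ran from a median of 0.38 in the shortest of 5 length groups of transcripts to -0.78 in the longest. Removing this length trend moved the sarcomere median from -2.04 to -2.32 (quartiles -2.71 and -1.83), so the trend does not account for the difference. Scaling to the reads outside the table gave -2.64. That scaling lowers all ratios of this comparison together (median of all genes by -0.57), so it could only enlarge the difference. Its outcome was fixed by the library totals and is no separate test. If a fixed share of Twist2 cells had completed the GFP response and the rest had stayed as in growth medium, every gene group would reach the same fraction of it. Mitosis and replication genes had reached a median of 89.2% of the way from the Twist2 growth medium level to the GFP differentiation level (bootstrap interval over genes 86.9% to 91.7%). Sarcomere genes had reached 23.9% (18.7% to 26.0%), a difference of 0.653 as a fraction. Coupling and metabolism genes lay at 35.0% and 36.0%. Some mitosis and replication genes lay far below their median, with a 10th percentile of 0.449 as a fraction. The outside-table scaling gave 87.6% for mitosis and replication genes and 15.8% for sarcomere genes. These values argue against that model only. They cannot decide on a share of completed cells where the rest also changed, because all these cells were in differentiation medium. An effect of Twist2 on the sarcomere genes may remain, as a hypothesis found and examined on the same 4 libraries. Without replicate libraries it was not tested.

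In growth medium, many muscle genes were lower with Twist2, which could reflect fewer cells that had begun to differentiate early. That alone was taken to leave nearly all lower genes among those that went up in GFP differentiation. Yet 54.8% of the 372 lower genes (204) were not at least 2-fold higher there. Differentiation was measured only at the end of the protocol, so a gene that rises early and falls again would be among these 204 too. The count therefore cannot decide whether fewer early differentiating cells account for all lower genes. For the sarcomere genes this explanation stays open as well. The 28 members with at least 10 CPM in the GFP library had log2 ratios with a median of -2.69 and an interquartile range of 1.09. That range lies between the bounds set for a common factor and against it. A smaller share of early differentiating cells and a direct effect of Twist2 thus cannot be told apart for the sarcomere genes.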
